A study of Mus musculus with 6 samples.

How the data were processed

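Total RNA of thioglycolate-elicited peritoneal macrophages of female BALB/c mice was measured on 6 Agilent mouse miRNA arrays with 1 colour, 3 of uninfected cells (control) and 3 of cells given heat-inactivated Candida albicans for 36 h (infected). All 6 arrays lay on 1 slide and shared 1 scan. The 3 control arrays and infected array 1 were in row 1 of the slide and infected arrays 2 and 3 in row 2. Per the file headers, the intensity values deposited by the authors were extracted with Agilent Feature Extraction 11.5.1.1. The deposited columns used here were the background-subtracted processed intensity of each spot, the median spot and local background intensities, the total signal per miRNA and the flags of spot quality and detection. No normalization between arrays was recorded in those headers or labels.

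The following was computed from those intensities. Each array design held 58594 spots. On control array 2, 3 damaged rows were left out and a further 2 spots were absent. Spots flagged as non-uniform or as population outliers were left out, between 2.68% and 3.69% of miRNA spots per array. The processed intensity was averaged over the remaining spots of a probe. A probe counted as detected where at least a share of 0.5 of its spots was well above background. Only 197 of 4415 probes were detected on all 6 arrays, so each array was divided by its 75th percentile over those 197 probes. Values were then set to a common floor, which was -4.28 on the log2 scale, and log2 was taken. Values at the floor have no order. Of several probes, the one with the highest mean signal represented its miRNA. For 112 tested miRNAs at least 2 probes were detected on 3 or more arrays. Of these, 11 had probes of opposite sign and 0 had probes more than 0.5 apart on the log2 scale. The other 58 tested miRNAs had only 1 such probe, so agreement between probes could not be seen for them. Among them were miR-6908-5p and miR-7221-3p, which passed the test described below.

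The 170 miRNAs whose probe was detected on at least 3 arrays were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, infected minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Files were read with the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The 19 miRNA lists, the rule for named miRNAs and the main test were set before the data were examined. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The lists tied to HMGB1, to C. albicans, to Toll-like receptor signalling and to cell types came from general knowledge and were not checked against a source. Named miRNAs were the 5 of each direction with the smallest p among those detected on all 6 arrays, because fewer than 5 passed in each direction, the 5 brightest miRNAs, and members of the lists, of which those with the smallest p are given. The called miRNAs miR-7235-5p and miR-7221-3p fall outside that rule and were chosen after their values were seen. Numbers of detected miRNAs were compared by a two-sided exact permutation test, whose smallest p with 3 arrays against 3 is 0.1.

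Alternatives were other scalings, normexp background, the deposited total signal, the mean of all probes, a lower floor, other filters, eBayes with trend and robust settings, array weights, slide row as a term, a fold threshold, other calls of detection and leaving out each array. The normexp alternative was planned on mean spot intensities; the median spot intensity was used in its place, with an offset of 50. Scaling on 9 bright control probes, and leaving out both infected array 1 and control array 3, each also with an estimated correlation for the lists, were chosen after seeing the data. Row 2 held only infected arrays, so with slide row as a term the contrast rests on infected array 1 against the 3 control arrays. The calculation of array weights stopped before its convergence tolerance was reached.

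The procedure was tested on simulated data for infected minus control, in 20 data sets of 170 tested miRNAs with 20 miRNAs changed 2-fold and 20 changed 4-fold. It recovered 61.8% of the 2-fold and 99.3% of the 4-fold changes. Of all its calls, 16.5% were of unchanged miRNAs, above the intended 5 in 100, a mean of 6.35 false calls per data set with 40 changed miRNAs. In 20 data sets with no changed miRNA there were 4 false calls in all, at most 1 in a data set. With the true scaling factors given in place of estimated ones this share was 4.48%, and with estimated factors the median log2 change of unchanged miRNAs had an SD of 0.20 over the data sets. In these simulations, error in the scaling factor moved all miRNAs of an array together and raised the number of false calls. A list shifted 2-fold, the let-7 family, was called in 20 of 20 data sets with camera at the preset correlation. The simulated noise was drawn separately for each miRNA, whereas the correlation estimated for that list in the data was 0.79. The count therefore does not show how often a list of correlated miRNAs would be called. The simulated noise also had the same variance on each array, whereas infected array 1 and control array 3 had the most variable spots. The shares recovered and the false calls thus hold for such noise only and cannot be set against the calls in the data.

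miRNA names are those of the array design. Of the 170 tested, 145 matched a single miRNA gene of the RefSeq list of assembly GRCm38.p6 by synonym and 25 did not. The file headers name build mm9, so that list served for names and neighbouring genes only and no coordinates are given. The labels do not say whether samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.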

Results

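The series asked how miRNAs regulate HMGB1, a nuclear protein that is released as an alarm signal, in infection by the yeast Candida albicans. Peritoneal macrophages drawn into the abdomen by thioglycolate were cultured from mice and either left uninfected (3 control arrays) or given C. albicans inactivated at 65 °C for 2 h (3 infected arrays, 36 h). The arrays carried probes for 1881 mouse miRNAs.

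Between 120 and 192 miRNAs were detected per array. The control arrays gave 166 ± 22.5 detected miRNAs (SD, n = 3 arrays) and the infected arrays 158 ± 33.0 (SD, n = 3 arrays), a difference of -8.33 that was not larger than the spread between arrays (exact permutation test, two-sided, p = 0.8, smallest possible p 0.1). The direction turned without control array 1 (4.50) and without infected array 1 (10.7), and the difference was -18.0 where 1 spot well above background was enough for detection. With any other array left out it was between -19.3 and -13.0. Infected array 1 had the fewest detected miRNAs, 120, and its 9 bright control probes had a median signal of 0.259 times that of infected arrays 2 and 3. Its correlation across tested miRNAs with the other arrays lay between 0.927 and 0.955, where miRNAs are not independent replicates. Infected array 1 and control array 3 also had the most variable spots, with median coefficients of variation of 21.7% and 25.4%, against 6.77% to 9.61% on the other arrays.

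**Figure D1:**
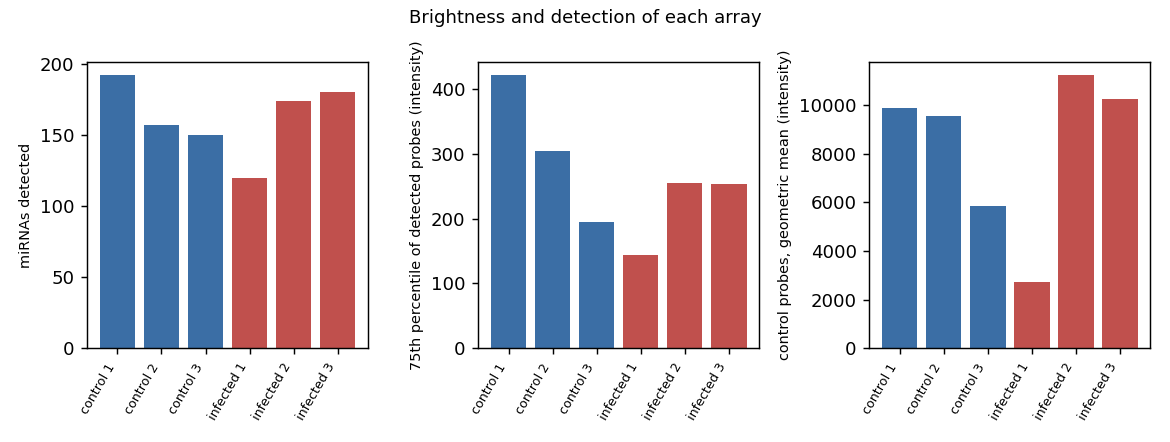
Bars show for each array the number of detected miRNAs, the 75th percentile intensity of the 197 probes detected on all arrays and the geometric mean intensity of 9 bright control probes, with control arrays in blue and infected arrays in red. Infected array 1 is lowest in each panel, with 120 detected miRNAs.

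Most of the signal came from the probe of miR-6366, which accounted for 67.5% of the summed signal of the brightest probe of each miRNA over the 6 arrays. The other 4 of the 5 miRNAs with the highest mean signal over all arrays were miR-494-3p, miR-1224-5p, miR-3963 and miR-8110, given here without an order, since probes differ in how brightly they report. Of these 5, only miR-494-3p passed the test between the groups.

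Heat-inactivated C. albicans was accompanied by lower miR-494-3p, a product of a large miRNA cluster, whose mean log2 signal was 5.46 ± 0.14 (SD, n = 3 control arrays) against 3.43 ± 0.75 (SD, n = 3 infected arrays). The change was -2.03 on the log2 scale (SE 0.33, limma adjusted p = 0.000764), so that control arrays were 4.07-fold brighter, and each infected array lay below each control array. miR-6908-5p, whose gene lies inside Pdxk, was lower by a log2 change of -1.87 (SE 0.36, limma adjusted p = 0.00313), which rests on 1 probe, since its other probe was not detected on any array. miR-188-5p, whose gene lies inside Clcn5, had a change of -1.37 (SE 0.36, limma adjusted p = 0.0401), with control arrays at 0.78, -0.92 and -0.33 and infected arrays at a mean of -1.52. In both, as in miR-494-3p, the 3 infected arrays lay below the 3 control arrays. The miR-494-3p call held with any 1 array left out, whereas that of miR-6908-5p ended without infected array 1 (adjusted p = 0.0793) and that of miR-188-5p without control array 1 (0.263), control array 3 (0.148), infected array 1 (0.112) or infected array 3 (0.0727). The miR-494-3p call ended under the 6 other settings that gave 0 calls, in which its log2 change was between -2.50 and -1.47 and its adjusted p between 0.0819 and 0.342. Under these 6 settings the calls of miR-6908-5p and miR-188-5p ended as well, and also with median scaling, control probe scaling, detection on at least 1 array and both dim arrays left out, and that of miR-188-5p with slide row as a term. Apart from leaving out each array, miR-6908-5p passed in 6 of 16 other settings, with log2 changes of -0.93 to -2.34 where it did not. The -0.93 came from the mean of all probes, where the undetected probe, at the floor on each array, made the change smaller. By the same count miR-188-5p passed in 5 of 16, with -1.10 to -1.86 where it did not.

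miR-7118-5p, whose gene lies inside Plxnb2, was higher in infected arrays by 1.11 on the log2 scale (SE 0.30, limma adjusted p = 0.0435), 2.17-fold. The other called miRNAs, chosen for naming after their values were seen, were near the limit of detection. miR-7235-5p, whose gene lies inside Tbkbp1, had a change of 1.53 (SE 0.30, limma adjusted p = 0.00313) and miR-7221-3p one of 0.99 (SE 0.27, limma adjusted p = 0.0438). Each was detected on 1 of 3 control arrays and 3 of 3 infected arrays, so the sizes of these changes depend on the floor. Over other settings they ranged from 0.37 to 2.15 for miR-7235-5p and from 0.28 to 1.14 for miR-7221-3p, whose other probe was detected on 1 array only. The miR-7118-5p call ended without control array 1 (adjusted p = 0.132), 2 (0.26) or 3 (0.14), that of miR-7235-5p without control array 2 (0.0546), and that of miR-7221-3p without any array other than infected array 1 (0.0919 to 0.26). Apart from leaving out each array, miR-7118-5p passed in 6 of 16 other settings, with changes of 0.64 to 1.13 where it did not, and miR-7235-5p and miR-7221-3p each in 5 of 15.

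**Figure D2:**
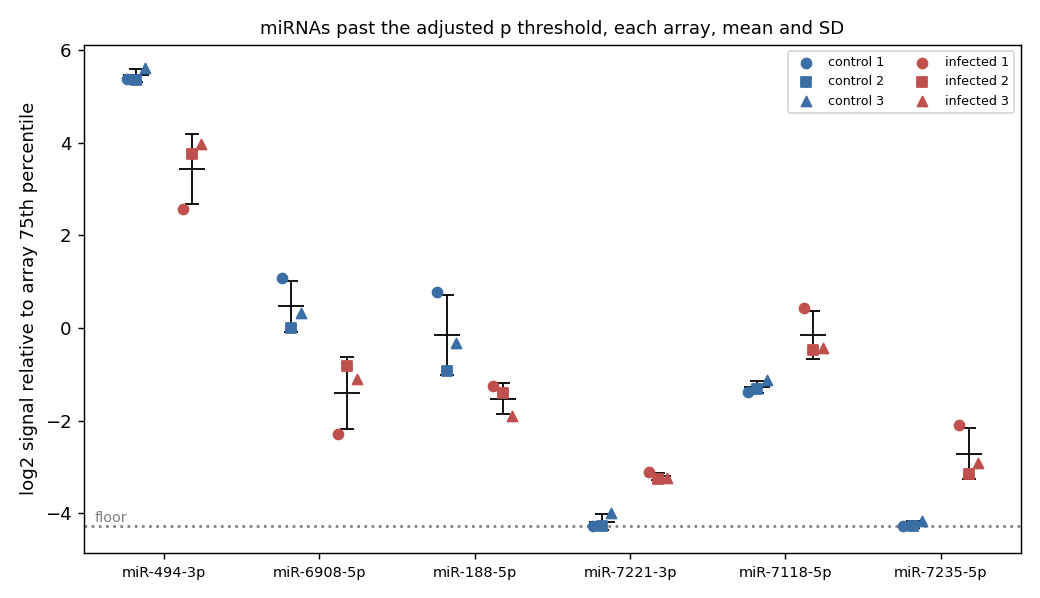
Points show the log2 signal of each array relative to its 75th percentile for the 6 miRNAs past the threshold, with control arrays in blue, infected arrays in red, marker shapes for replicates, black bars for the mean and SD, and a dotted line at the floor of -4.28. For each miRNA the 3 infected arrays lie on one side of the 3 control arrays, and miR-7235-5p and miR-7221-3p lie at or near the floor in control arrays.

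In all, 6 of 170 tested miRNAs passed, 3 lower and 3 higher. At an unadjusted p under 0.05 there were 20, of which 13 were higher and 7 lower. In 30 miRNAs (17.6%) the groups did not overlap, where chance gives 10% for a single miRNA. The miRNAs share the arrays and their scaling factors, and 137 of the 170 changes were positive. The 2 shares are therefore not a test of an excess. The median log2 change of all tested miRNAs was 0.20, and it became -0.18 with scaling over all probes and -0.21 without scaling. The zero point of the changes thus depended on the scaling, and the p-values given test against 0, not against this median. With scaling by the median over detected probes, only miR-494-3p of the 6 kept its call. Relative to the median change of 0.20, miR-494-3p changed by -2.23, miR-6908-5p by -2.07 and miR-188-5p by -1.57. On the higher side miR-7118-5p changed by 0.91, miR-7235-5p by 1.33 and miR-7221-3p by 0.79. The number of calls was 0 with scaling over all probes, with quantile normalization, without scaling, with the deposited total signal, with the mean of all probes and without a filter, while it was 27 with array weights. It was 25 with slide row as a term, a contrast that rests on infected array 1, the dimmest, against the 3 control arrays, because row 2 held only infected arrays. It was 3 without control array 1, 3 without control array 2, 3 without control array 3 and 11 without infected array 1. Without infected array 1 the groups were also fully divided by slide row, with infected arrays in row 2 and control arrays in row 1.

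Next in rank among miRNAs detected on all arrays, without passing, were miR-680 with a log2 change of 0.89 (limma adjusted p = 0.156), miR-3960 with 0.93, miR-7040-5p with 0.73 and miR-211-3p with 0.86 on the higher side. On the lower side were miR-6769b-5p with -0.99 (limma adjusted p = 0.131) and miR-1224-5p with -0.75.

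Of 23 miRNAs on the array that earlier work has tied to HMGB1, 10 were detected on any array and 8 were tested. The other members could not be tested. Of the 8, 0 passed over all miRNAs tested and 0 when adjusted over the list alone. The smallest p of the list belonged to let-7f-5p, with a log2 change of 0.54 (SE 0.29, limma adjusted p = 0.391), and miR-22-3p had 0.54 (SE 0.33). The list's median lay -0.01 from that of all tested miRNAs, and its camera adjusted p was 0.833. All 8 members had positive changes, a sign that turned in 6 of them with scaling over all probes. Without control array 1, 4 of the 8 were positive. The median change of the list was 0.19, against -0.0079 without control array 1 and 0.42 without infected array 1.

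The list of miRNAs widely held to rise in macrophages after Toll-like receptor signalling had 21 members on the array. It counted both strands of most of its miRNAs, so these are not 21 separate miRNAs held to rise. Of the 21, 7 were detected on any array and 5 were tested. Of these 5, 0 passed, also when adjusted over the list alone (camera adjusted p = 0.653). Among the tested ones were miR-155-5p, a regulator of inflammatory signalling, with a log2 change of 0.46 (SE 0.31, limma adjusted p = 0.497), and miR-146a-5p, a brake on that signalling, with 0.07 (SE 0.32, limma adjusted p = 0.905). Without control array 1 the median change of this list was 0.15 in place of 0.46, and 3 of 5 members were positive in place of 5. miR-221-3p had a change of 0.55 and miR-21a-5p one of 0.54, where their other probes gave 0.21 and 0.30. The other probe of miR-146a-5p, detected on 3 arrays, gave 0.42, and that of miR-155-5p was not detected. Without scaling the value of miR-155-5p was -0.021, and that of miR-146a-5p was below 0 without scaling and with scaling by all probes, by quantiles, by the median and by control probes. Of the 3 tested miRNAs reported to rise with C. albicans in mouse macrophages, 0 passed (camera adjusted p = 0.787), and miR-125a-5p had a change of 0.37. Of the miR-99b, let-7e and miR-125a cluster, 3 were tested and 0 passed (camera adjusted p = 0.653), with miR-99b-5p at 0.28 and let-7e-5p at 0.67. miR-99b-5p lay near the floor on control array 1, and its other probe, detected on 1 array, gave 0.084. Without control array 1 the median change of this cluster was 0.11 in place of 0.37.

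The let-7 family had 9 tested members, 9 with positive changes and 0 past the threshold, also when adjusted over the list alone. Its median change lay 0.34 above that of all tested miRNAs (camera p = 0.0372, adjusted p = 0.363, and adjusted p = 0.948 with an estimated correlation). The smallest p was that of let-7e-5p, and let-7b-5p had a change of 0.60 (SE 0.31). Without control array 1, let-7e-5p had a change of 0.34 in place of 0.67 and let-7b-5p one of 0.28, the family median lay 0.19 above that of all tested miRNAs, and 7 of the 8 members then tested were positive. The camera p was 0.274 without that array, 0.177 without infected array 1 and 0.00599 without control array 3 (adjusted p = 0.0599). With scaling over all probes 6 of 9 members stayed positive, and 8 of 9 remained above the median of all tested miRNAs. The miR-29 family had 3 tested members, 3 positive and 0 past the threshold, with miR-29a-3p at 0.67 and miR-29b-3p at 0.60 (camera adjusted p = 0.363). The remaining member, miR-29c-3p, was detected on 3 arrays only, so its change of 0.52 rests in part on values not well above background. Scaling on control probes, an alternative chosen after seeing the data, gave this family a camera adjusted p of 0.0203, and leaving out infected array 1 and control array 3, also chosen then, gave 0.0441, in a range of 0.0203 to 0.994 over all settings that tested it at the preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.903 and adjusted p = 0.731), and under the main scaling that adjusted p was 0.948.

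Of the miR-23, miR-27 and miR-24 clusters 5 were tested, with miR-23b-3p at 0.61 and miR-27b-3p at 0.56, and 0 passed. miR-27b-3p was detected on 4 arrays only and its other probe on 0, so its change rests in part on values not well above background. Of the miR-17/92 cluster and its paralogs 10 were tested and 0 passed, with miR-18a-5p at -0.24 and miR-106b-5p at 0.20 (-0.055 and 0.021 by their other probes), and 0 of 10 lay above the median of all tested miRNAs. Lists of alternative activation (4 tested) and of the miR-15/16 family (3 tested) also held 0 miRNAs past the threshold, and 0 of the 10 lists tested passed with camera at either correlation or with fry, where 1 had an unadjusted camera p under 0.05. Lists with fewer than 3 tested members were the miR-30 family (2), the hypoxia miRNA miR-210 (1), the list for the Sfmbt2 cluster (2), myeloid miRNAs (1) and lymphocyte markers (2, of which miR-181a-5p had a change of 0.21), and 0 of their members passed. miR-181a-5p lay at the floor on control array 1, and its other probe was not detected on any array. The list for the Sfmbt2 cluster was drawn by miRNA name, not by locus, so its members need not come from that cluster.

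Markers of most other cell types were below detection, as were most miRNAs of the array (120 to 192 of 1881 detected per array). Lists with 0 detected members therefore do not show that those cells were absent. Of the lymphocyte list 2 of 4 were detected, miR-181a-5p and miR-181b-5p. Of the epithelial list 0 of 7 miRNAs on the array were detected on any array, of the endothelial list 0 of 2, of the red cell list 0 of 4 and of the fibroblast and smooth muscle list 0 of 8. Of the myeloid list 1 of 4 was detected, miR-142a-3p, while miR-223-3p, a miRNA of the myeloid lineage, was not detected on any array.

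**Figure D3:**
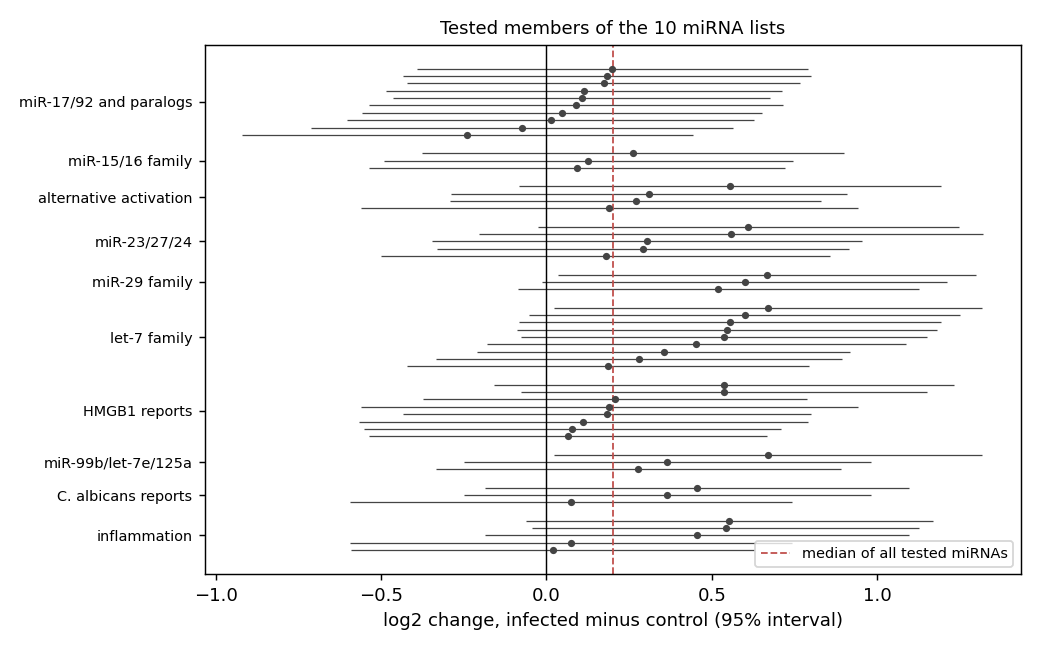
Points show the log2 change, infected minus control, with its 95% interval, for each tested member of the 10 lists tested, with a dashed line at the median of all tested miRNAs, 0.20. The 9 let-7 members have positive changes under this scaling, of which 6 stay positive with scaling over all probes, and 0 members of any list passed the threshold.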

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

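miR-32-3p was outside the test because it was detected on 2 arrays, both infected, and on 0 control arrays. Its mean intensity over the infected arrays was 14.7 and over the control arrays 13.9, so it lay above the control level by less than the spread between arrays. The single values were 8.10, 19.7 and 16.1 on infected arrays and 13.4, 16.6 and 11.6 on control arrays, which overlap. Detection here refers to the probe that represents each miRNA. Among the 29 miRNAs whose representing probe was detected on 1 or 2 arrays only, miR-182-5p was likewise detected on 2 infected and 0 control arrays. Its mean over infected arrays was not above that over control arrays. The reverse, 2 control and 0 infected arrays, held for miR-1906 and miR-7058-5p. The intensities of miR-7058-5p were 48.2, 19.5 and 13.6 on control arrays and 3.79, 12.7 and 11.7 on infected arrays, which do not overlap. These intensities are not scaled between arrays, infected array 1 was the dimmest, and 0 of these differences were tested.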

How the results depend on the processing

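No paired analysis was possible because the labels give the samples no replicate numbers; those used here only name the arrays. Scaling on control probes and leaving out both dim arrays (infected 1 and control 3) were chosen after seeing the data. The cause of the differences was not tested. Of the 170 tested miRNAs, 113 were detected on all 6 arrays, so the others had values not well above background. With slide row as a term, the contrast rests on infected array 1, the dimmest, against the 3 control arrays. Against 6 calls there were 0 with scaling over all probes, quantile normalization, no scaling, the deposited total signal, the mean of all probes and no filter, 1 with each of median scaling, control probe scaling and leaving out both dim arrays (0 higher and 1 lower each), 3 with detection on at least 1 array (2 higher, 1 lower), 25 with slide row (17 higher, 8 lower) and 27 with array weights (22 higher, 5 lower). Leaving out each array gave 3 to 11 calls. Numbers within 1.5 times came from normexp (7), the lower floor (6), detection on all 6 arrays (5), trend and robust (8) and at least 2-fold (5). miR-494-3p passed in 16 of 22 alternatives, among them each of 6 with 1 array left out, and kept its sign in 22 (log2 change -2.88, with slide row, to -1.47, adjusted p 1.24e-17 to 0.342). miR-6908-5p passed in 11 of 22, miR-7118-5p in 9 of 22, miR-188-5p in 7 of 22, miR-7235-5p in 10 of 21 and miR-7221-3p in 6 of 21, each with 1 sign throughout. miR-7235-5p and miR-7221-3p had no value with detection on all 6 arrays. Lists past the threshold stayed at 0 except for 1 with control probe scaling and 1 without both dim arrays, the miR-29 family in each at the preset correlation. With an estimated correlation both settings gave 0 lists (smallest adjusted p 0.903 and 0.731). The difference in detected miRNAs ranged from -19.3 to 10.7 with 1 array left out, and was -18.0 (permutation p = 0.4) with detection by at least 1 spot and -6.67 (0.9) by the deposited call per miRNA.

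Signs turned for uncalled miRNAs as follows. With scaling over all probes the log2 changes were -0.027 for miR-6366, -0.073 for miR-125a-5p, -0.16 for miR-99b-5p, -0.21 for miR-3963, -0.10 for miR-181a-5p, -0.24 for miR-106b-5p and -0.36 for miR-146a-5p. Without scaling they were -0.021 for miR-155-5p, -0.064 for miR-6366, -0.11 for miR-125a-5p, -0.19 for miR-99b-5p, -0.25 for miR-3963, -0.094 for miR-181a-5p, -0.28 for miR-106b-5p and -0.40 for miR-146a-5p. miR-106b-5p had -0.054 with quantile normalization, -0.12 with the total signal and -0.0021 with control probe scaling. miR-146a-5p had -0.14, -0.12 and -0.13 in these, -0.12 with median scaling and -0.61 with slide row. With slide row miR-22-3p had -0.31, miR-27b-3p -0.55 and miR-3963 -0.15. miR-18a-5p had 0.11 with normexp, 0.054 with array weights and 0.058 without both dim arrays. With 1 array left out, miR-106b-5p ranged from -0.0035 to 0.31, miR-146a-5p from -0.14 to 0.41 and miR-18a-5p from -0.44 to 0.13. Of the values of the 26 uncalled miRNAs, 20 of 411 passed under other settings and 5 of 156 with 1 array left out.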

Other observations

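All tests of explanations given here, with their thresholds, were chosen after the values they rest on had been seen, so they cannot bear an explanation out. Where an explanation is said to be argued against, that rests on the printed values, not on a prediction made in advance.

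The genes around Mir494 form a cluster of 39 miRNA genes when genes within 10 kb of one another are joined. Of the 75 other mature miRNAs of that cluster on the array, 1 was detected, miR-3072-5p, with a log2 change of 0.41 (limma adjusted p = 0.548), while miR-494-3p was among the 5 brightest miRNAs of these arrays. Around Mir188, 2 of 9 other miRNAs were detected on 3 or more arrays, miR-500-3p with a change of 0.17 and miR-532-3p with 0.29, and neither passed.

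For the lower miR-494-3p, dimness of infected array 1 alone was argued against by a log2 change of -1.60 (SE 0.14) without that array. Without it, the infected arrays all lay in slide row 2 and the control arrays in row 1. Dimness together with a difference between slide rows is therefore not argued against. A single faulty probe was argued against by the other probe of this miRNA, which changed by -2.08 (SE 0.47), although both probes may bind the same other RNA, which was not tested. A difference between slide rows stays open: in row 1 the infected array lay at -2.79 from the lowest control array, but this is 1 array, and the dim one. Exposure to heat-inactivated C. albicans, a biological explanation that the design allows, also stays open. The source labels give a time, 36 h, for infected arrays only, so time in culture could not be compared between the groups.

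For the lower miR-188-5p and miR-6908-5p, an axis that also parts the control arrays stays open, since the range of the control arrays was 1.24 times the fall for miR-188-5p and 0.578 times for miR-6908-5p. Control array 1 alone was argued against as the whole cause for miR-6908-5p, whose log2 change without it was -1.56 (SE 0.37, limma adjusted p = 0.0282). For miR-188-5p it stays open, with a change of -0.90 (SE 0.31, limma adjusted p = 0.263) without it. A single faulty probe was argued against for miR-188-5p, whose 3 other probes had changes of -1.55 to -1.42 (largest SE 0.51), and stays open for miR-6908-5p, whose other probe was detected on 0 arrays. Exposure to heat-inactivated C. albicans stays open for both.

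For the higher miR-7235-5p, miR-7118-5p and miR-7221-3p, the dim infected array 1 was argued against as the whole cause for miR-7118-5p, detected on all arrays, by a log2 change of 0.81 (SE 0.12) without it. Without that array the contrast sets slide row 2 against row 1, so dimness together with a row difference is not argued against. For miR-7235-5p and miR-7221-3p the dim array stays open as a cause, since their control values lie at or near the floor. Their median change of 0.99 without that array is therefore not held against it. Division by smaller scaling factors stays open, with a median change of 0.64 (largest SE 0.35) and 0 calls without scaling. A single faulty probe was argued against for miR-7118-5p, whose other probe had a change of 1.14 (SE 0.31), and stays open for miR-7235-5p and miR-7221-3p, whose values lie near the floor: the other probe of the former, detected on 4 arrays as the main one was, had a change of 1.26 (SE 0.30), and that of the latter was detected on 1 array. Exposure to heat-inactivated C. albicans stays open as well.

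Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many as 6 changed miRNAs, the real one, and the highest of the others gave 0. So few splits cannot give a share under 0.05.

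A further hypothesis was that changes between the groups run along an axis that also parts control arrays. Across the 170 tested miRNAs, which are not independent replicates, control 1 minus control 2 and the infected mean minus control 3 had a Pearson r of -0.24 and a Spearman rho of -0.01. The other 2 arrangements of the control arrays gave r of -0.24 and -0.0046, so the test leaves the hypothesis open.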
